A study of Mus musculus with 8 samples.

How the data were processed

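Per the labels, lungs of C57BL/6 recipient mice were taken after 3 days of hypoxia. Per the labels' protocols, mRNA was isolated with oligo(dT) magnetic beads, made into libraries with a KAPA kit (strand not stated) and sequenced as 75 bp single reads on a HiSeq 2500. Per the submitters' processing notes, base calls came from CASAVA 1.8.2, reads were aligned to mm10 with TopHat2 2.0.13 and Bowtie2 2.2.3, SAMtools 0.1.19 handled the alignments, and Cufflinks 2.2.1 gave the gene values. The gene annotation, settings and filters of these steps are not given in the sources used here. The groups were read from the sample titles, because the series' design text names NOS-null marrow for both groups.

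The deposited gene table used for all main results holds signal values on the read count scale, which the authors had divided by 1 size factor per library, in the column style of Cuffnorm, a part of Cufflinks. The deposited FPKM table, made by the authors with the same tools, was used only as an alternative. Within a library 98.8 to 98.9% of positive values lay within 0.05 of a whole multiple of a step of 0.937 to 1.088, taken as the value of 1 read. From 8 to 15 values per library lay below this step, so whole read counts were not taken as recovered. No count model was used for the gene tests. The counting intervals given for Ifi202b, Hal and BC018473 take values divided by this step and rounded as reads.

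The count-scale table lists 23284 genes, 3543 of them at 0 throughout. Values were used as scaled by the authors, increased by 1 and log2-transformed. The 14008 genes with a value of at least 10 in at least 4 libraries were tested with limma (version 3.58.1, trend on, not robust, R 4.3.3), NOS-null marrow minus WT marrow, without other terms. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Intervals are 95% intervals from the same fit. No batch or date is given in the labels used here, so none was modelled.

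The study's gene lists, 49 in number, were written down from general knowledge of the genes. They were tested with limma's camera at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the 45 lists with at least 5 tested genes. Camera with a correlation estimated for each list and fry were run beside it. The mean deviation of a list in a library is the mean over its tested genes of log2 value minus the gene's mean over the 8 libraries. Gene positions came from GRCm38, the same assembly as mm10, and 23040 of the 23284 table symbols were matched. Windows of 10 Mb around the Nos genes were compared by a two-sided Fisher's exact test.

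Genes are named by rule. These are Nos1, Nos2 and Nos3, and the 12 largest changes up and the 12 down among changed genes with separated groups and a mean of at least 20, leaving out names that are clone or model identifiers. For each list past camera's threshold or with at least 2 changed members the 4 genes of smallest p are eligible, and for other lists the 2 of highest mean. A few sex-linked genes serve as a sample check.

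The procedure was tested on simulated values, drawn with the means and variability of these data, in which the changed genes are known (14043 tested). It recovered 26 of 67 genes changed by 1.5-fold (38.8%), 51 of 67 changed by 2-fold (76.1%) and 60 of 66 changed by 4-fold (90.9%). Of 146 genes it called, 9 had not been changed, and it called 0 when none was changed. It recovered 6 of 6 shifted lists and called 0 of 33 unshifted lists. The simulated genes varied independently of each other, so this does not measure false calls of lists whose genes vary together. Estimated correlations within a list reached 0.86 in these data, for neutrophil and ribosomal protein genes. With the real libraries split into wrong groups of 4 and 4, up to 23 lists were called.

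Reads of near-identical genes, among them globin, Klra, tubulin, Gimap, Cyp2a, Ifi200, H2 and Amd1 or Amd2 genes, can be split or moved between copies, so values of such genes are uncertain. Genes that overlap others on the opposite strand are uncertain for the same reason. The share of donor cells in the lungs was not measured here.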

Results

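RNA from whole lungs of 8 C57BL/6 wild-type (WT) mice was sequenced after a bone marrow transplant and 3 days of hypoxia. In 4 mice the donor marrow carried null alleles of all 3 nitric oxide synthases, the neuronal (Nos1), inducible (Nos2) and endothelial (Nos3) enzymes (called NOS-null marrow here). In the other 4 mice the donor marrow was WT (called WT marrow). The recipients' own lung cells kept the 3 genes, so a change in whole lung adds up donor-derived blood and immune cells and the recipient tissue around them. The series title places the work in the study of nitric oxide synthases of myeloid cells in pulmonary hypertension brought on by hypoxia. Lungs kept in normal air were not analysed here, so no value measures the response to hypoxia itself.

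The values of a library summed to 7767065 to 8625142, and 16778 to 17621 genes had a value above 0. The secretoglobin gene Scgb1a1 of airway club cells was the highest gene in every library, with 1.68 to 2.36% of the total. Values are read counts scaled between libraries by the authors, called scaled reads, and are given as mean ± SD with n = 4 libraries per group. Log2 changes are NOS-null marrow minus WT marrow on the scale of log2(scaled reads + 1), which understates the change of low genes, and are given with their standard error (SE). The labels do not say how the replicates of a group relate beyond naming mice, so the p-values measure the spread between these samples. On the first principal component, which held 49.2% of the variance, the 4 NOS-null marrow libraries lay at −57.7, −32.3, −3.35 and −1.41 (replicates 1 to 4 in turn) and the 4 WT marrow libraries between 17.7 and 27.2. NOS-null marrow replicates 1 and 2 therefore stood farther from WT marrow on this component than replicates 3 and 4.

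Genes lower with NOS-null marrow included the contractile smooth muscle genes Acta2 and Tagln, the matrix gene Tnc, the chemokine gene Cxcl12, the DNA replication gene Mcm2 and the natural killer (NK) cell gene Gzma. Genes higher included the erythroid gene Alas2, the p53 target Cdkn1a, the interferon-induced gene Rsad2 and the cytokine-like matrix gene Spp1. Of 14008 genes tested with limma, 567 passed a Benjamini-Hochberg adjusted p of 0.05, 262 of them higher and 305 lower with NOS-null marrow. Among these, 76 were higher and 47 lower by at least 2-fold. In 563 of the 567 the 4 values of 1 group all lay above the 4 of the other, and 2398 of all tested genes (17.1%) were separated in this way, where chance gives 2.86%. The count fell to 95 without NOS-null marrow replicate 2 and to 71, 81, 87 and 233 without WT marrow replicates 1, 2, 3 and 4. Without both NOS-null marrow replicates 1 and 2 it was 181, of which 144 were among the 567. Without NOS-null marrow replicate 4 the genes higher numbered 411.

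**Figure D1:**
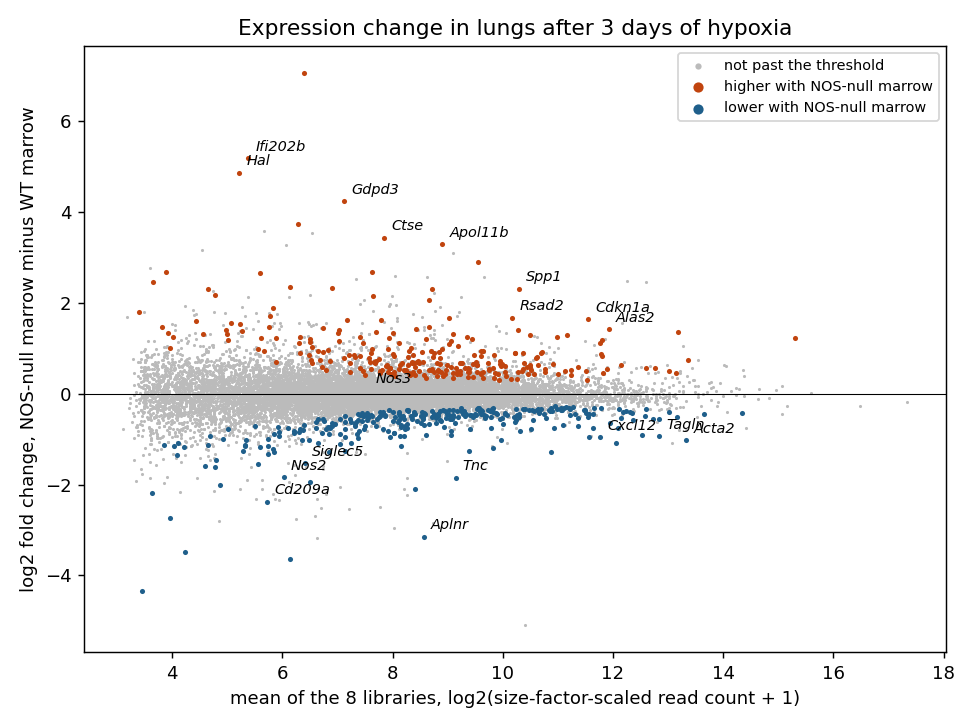
Log2 change of each of the 14008 tested genes (vertical axis, NOS-null marrow minus WT marrow) against log2(mean scaled reads over the 8 libraries + 1) (horizontal axis). Orange points are the 262 genes higher and blue points the 305 genes lower at an adjusted p under 0.05, grey points are the rest, and labels name genes given in the text.

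The deleted genes were measured first. Nos2, which encodes the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960226, GRCm38), was lower in all 4 NOS-null marrow libraries. It stood at 13.3, 20.8, 40.4 and 43.5 scaled reads in replicates 1 to 4, against 87.4 to 115 in WT marrow. The means were 29.5 ± 14.8 and 98.6 ± 13.2 (log2 change −1.84, SE 0.33, adjusted p = 0.0221, and 0.000434 adjusted over the list alone of tested Nos genes). Nos3, the endothelial enzyme's gene (chromosome 5, 24364816 to 24384474), stood at 194 ± 18.0 against 184 ± 15.8 (log2 change 0.07, SE 0.11, 95% interval −0.17 to 0.30, adjusted p = 0.701, and 0.526 adjusted over the list alone). Nos1 (chromosome 5, 117866839 to 117958840) was listed at 0 in every library except NOS-null marrow replicate 4, where it stood at 1.088, the step taken as 1 read. It was not tested, and at this depth a value of 0 does not exclude a level under 2.81 to 3.26 scaled reads per library (3 reads, counting error only). The Nos2 call was lost without NOS-null marrow replicate 2 (adjusted p = 0.0717) and without WT marrow replicates 1, 2, 3 and 4 (adjusted p = 0.0744, 0.0677, 0.0605 and 0.053). Over all 8 fits that left out 1 library its log2 change ran from −2.08 to −1.53.

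Other genes of nitric oxide synthesis and signalling went both ways. Of 23 tested, 1 rose, 1 fell and 21 did not pass, and adjusted over the list alone 2 rose and 3 fell. The riser was Prkg2, a cGMP-dependent protein kinase gene (log2 change 0.67, SE 0.14, adjusted p = 0.035), and Nos2 was the gene that fell. Arg2, an arginase gene, stood at 195 ± 133 against 63.7 ± 17.1 (adjusted p = 0.0704), and Nostrin, a gene for a protein that binds endothelial nitric oxide synthase, at 1017 ± 52.8 against 1246 ± 72.9 (adjusted p = 0.0521). As a whole the list did not differ from other genes (camera adjusted p = 0.997), with a median log2 change of 0.07 and a mean of −0.04. Prkg2 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (highest adjusted p = 0.114).

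Ifi202b, an interferon-inducible gene, had the largest increase among the called genes named for their size of change. It stood at 79.9 ± 43.7 scaled reads with NOS-null marrow and 1.20 ± 0.93 with WT marrow (log2 change 5.19, SE 0.45, adjusted p = 0.000975). The WT marrow value rests on 5 reads over 4 libraries, each library under 3 reads. For this reason the ratio of the pooled reads is given, 66.2 with an exact 95% counting interval of 28.1 to 205. Donor DNA of another strain was not tested as a source of the Ifi202b difference. Hal, which encodes histidine ammonia-lyase, rose from 1.44 ± 1.22 to 71.0 ± 46.8 (4.87, SE 0.50, adjusted p = 0.00205). It held 6 reads in WT marrow, and its ratio was 49.1 (22.3 to 135). Both counting intervals cover counting error only and leave out the spread between mice. Gdpd3, a glycerophosphodiester phosphodiesterase gene, rose from 11.7 ± 5.18 to 265 ± 186 (4.24, adjusted p = 0.00205). Ctse, the gene of the protease cathepsin E, rose from 37.23 ± 16.97 to 421 ± 215 (3.44), and Apol11b from 80.8 ± 19.3 to 876 ± 425 (3.30, adjusted p = 0.00205 for each). Spp1, which encodes osteopontin, rose from 404 ± 72.8 to 2111 ± 856 (2.31, SE 0.26, adjusted p = 0.00253). The p53 target Eda2r (2.34) was also among the largest. A further 4 were Igj, now Jchain, the joining chain of secreted antibodies (2.89), Pira1 (2.68), Galntl2, now Galnt15 (2.65), and the formyl peptide receptor gene Fpr2 of neutrophils and other myeloid cells (2.31). These 4 did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1, 2 and 3, nor, except for Galntl2, without WT marrow replicate 4 (highest adjusted p = 0.137, 0.137, 0.103 and 0.106). Igj also did not pass without NOS-null marrow replicate 3. NOS-null marrow replicate 1 held 1115 scaled reads of Pira1 and 1864 of Fpr2, against at most 128 and 445 in the other 3, and both passed without it (log2 change 1.86 and 1.70, adjusted p = 0.0014 and 0.00706).

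Aplnr, the apelin receptor gene, had the largest decrease among the called genes named for their size of change. It stood at 61.9 (32.8 to 105.5) against 695 ± 750 (log2 change −3.15, SE 0.58, adjusted p = 0.0245). WT marrow replicate 3 alone held 1819 scaled reads while the other 3 WT marrow libraries held 282 to 355. Cd209a, a dendritic cell lectin gene, was at 17.5 ± 9.57 against 86.5 ± 16.2 (−2.37, SE 0.34, adjusted p = 0.00947). Tnc, the gene of the matrix protein tenascin C, fell from 870 ± 91.2 to 260 ± 114 (−1.85, SE 0.27, adjusted p = 0.0108). Siglec5, the table's symbol for the lectin gene Siglecf of eosinophils and alveolar macrophages, fell from 125 ± 17.4 to 43.1 ± 7.91 (−1.52, SE 0.17, adjusted p = 0.00248). Kmo, which encodes kynurenine 3-monooxygenase, fell from 69.2 ± 14.1 to 23.2 ± 6.02 (−1.55, adjusted p = 0.00962). The other genes among the 12 were Nos2, Wisp1, now Ccn4 (−2.11), Sprr1a (−2.02), Fcrls (−1.94), the NK receptor gene Klrb1c (−1.62), Lrrc3b (−1.58) and Mcoln3 (−1.46). The 6 other than Nos2 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate, nor Klrb1c without NOS-null marrow replicate 3 (adjusted p up to 0.125). Aplnr did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1 and 2 (highest adjusted p = 0.0796). A further 15 genes higher and 14 lower that passed carry only clone or model identifiers.

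**Figure D2:**
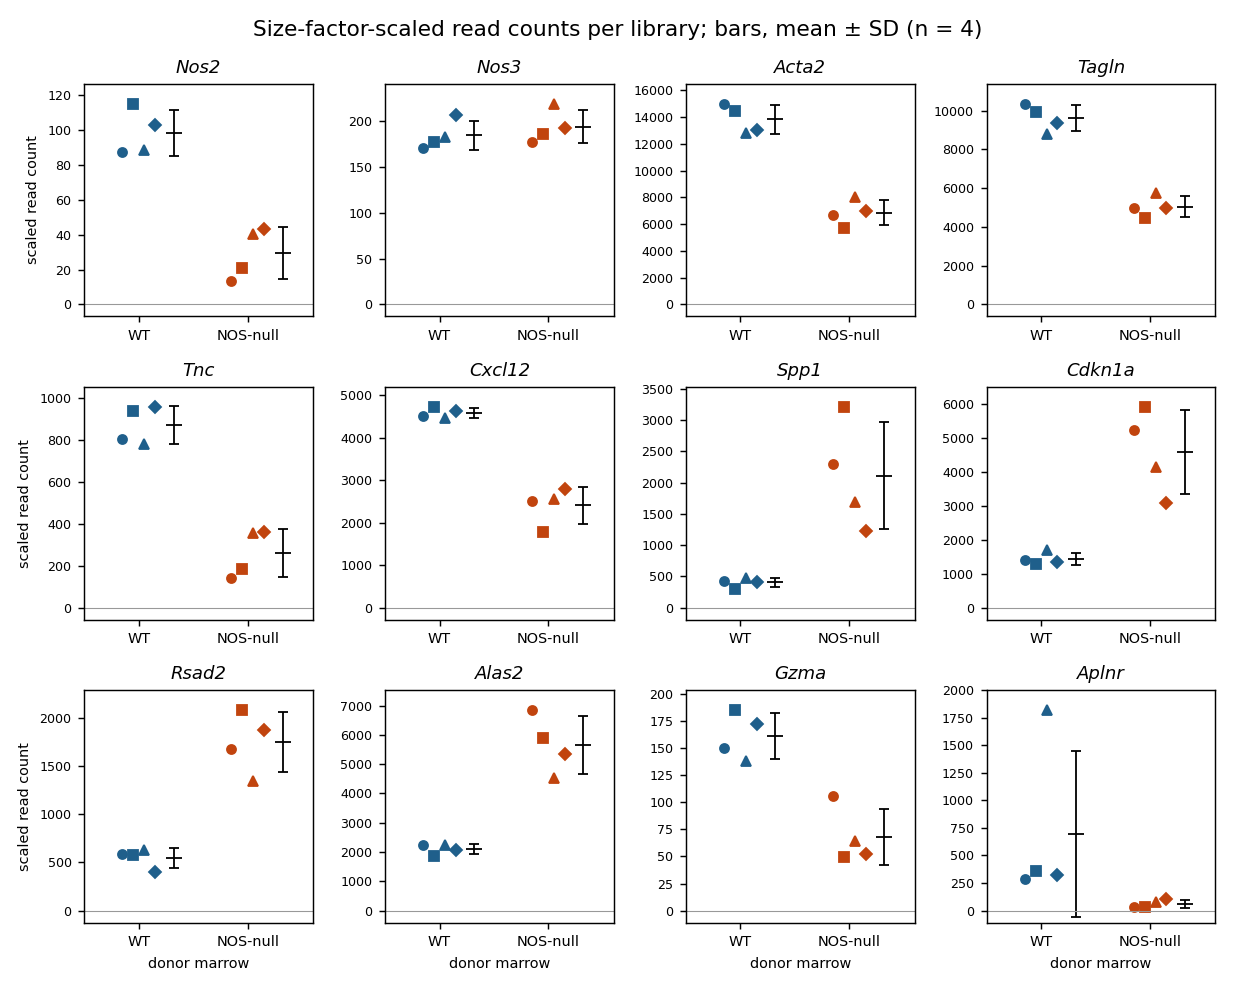
Scaled reads of 12 genes in each of the 8 libraries (vertical axes, linear and starting at 0 apart from the margin) by donor marrow, with circles, squares, triangles and diamonds for replicates 1 to 4 and bars for mean ± SD (n = 4). Nos3 overlaps between the groups, Aplnr has 1 WT marrow library at 1819, and each of the other 10 genes separates the groups.

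Vascular and matrix genes were tested as lists fixed in advance. Of 15 smooth muscle contractile genes, 6 fell, none rose and 9 did not pass. Acta2, smooth muscle actin, fell from 13816 ± 1056 to 6838 ± 941 (log2 change −1.02, SE 0.11, adjusted p = 0.00248). Tagln, transgelin, fell from 9609.6 ± 678 to 5043 ± 536 (−0.93, adjusted p = 0.00205), and Myl9, a myosin light chain gene, from 3532 ± 49.6 to 2479 ± 200 (−0.51, adjusted p = 0.00947). Des, Cnn1 and Cald1 also fell, while the smooth muscle myosin gene Myh11 (−0.17, adjusted p = 0.309) and Mylk (−0.07, adjusted p = 0.547) did not pass. Mean deviations of the contractile list were −0.20, −0.10, 0.00 and −0.19 in NOS-null marrow replicates 1 to 4 against −0.01 to 0.27 with WT marrow. The list was lower than other genes (camera adjusted p = 0.002), and the call was not kept at adjusted p = 0.69 with an estimated correlation. In all, 7 fell and 1 rose adjusted over the list alone. Des did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1 and 2 (highest adjusted p = 0.0731).

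Extracellular matrix genes were lower as a list of 23 (median log2 change −0.45, camera adjusted p = 0.00439, and adjusted p = 0.69 with an estimated correlation). Tnc and Postn, which encodes periostin (8635 ± 664 to 5906 ± 862, −0.56, adjusted p = 0.0316), fell, and Spp1 rose against them, while 20 did not pass. In all, 12 fell and 2 rose adjusted over the list alone. NOS-null marrow replicate 1 had the lowest mean deviation of this list from the mean of the 8 libraries. It was −0.58 on the log2 scale, against −0.07 to 0.05 in replicates 2 to 4 and 0.09 to 0.19 with WT marrow, and without it the list's median was −0.28. Postn did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (highest adjusted p = 0.107).

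Genes of vasoactive and growth factor signalling tied to pulmonary hypertension, hypoxia-inducible factor (HIF) targets with glycolysis, endothelium and pericytes did not move as lists (camera adjusted p = 0.441, 0.403, 0.202 and 0.666). Of 33 vasoactive genes tested, 2 rose, the angiotensin receptor gene Agtr1a (0.72, adjusted p = 0.0442) and the endothelin receptor gene Ednrb (0.44, adjusted p = 0.0457), and 2 fell, Aplnr and Pdgfa (−0.51, adjusted p = 0.0481). In all, 9 rose and 5 fell adjusted over the list alone, and the list's median (0.08) and mean (−0.03) differed in sign. Of 30 HIF and glycolysis genes, 2 fell, Loxl2, a matrix cross-linking enzyme gene (−1.01, adjusted p = 0.0146), and Tpi1, a glycolytic enzyme gene (−0.44, adjusted p = 0.0296). Of the HIF and glycolysis genes 3 rose and 4 fell adjusted over the list alone. Of 20 endothelial genes, Emcn, endomucin, fell from 1249 ± 106 to 551 ± 127 (−1.21, SE 0.16, adjusted p = 0.00721) together with Aplnr. Vwf, von Willebrand factor, rose from 2473 ± 410 to 4579 ± 855 (0.88, adjusted p = 0.0191) together with Ednrb, and adjusted over the list alone 4 rose and 2 fell. Of 11 pericyte genes, Postn and Higd1b (−0.46, adjusted p = 0.0425) fell, with 2 rising and 2 falling adjusted over the list alone. Among these genes Emcn passed in each of the 8 fits that left out 1 library. Loxl2 did not pass without WT marrow replicates 1 and 2 (highest adjusted p = 0.0606), and Tpi1 and Vwf not without these, WT marrow replicate 3 or NOS-null marrow replicate 2 (0.0896 and 0.0744). Agtr1a, Ednrb, Pdgfa and Higd1b did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (adjusted p up to 0.144). Agtr1a and Ednrb also did not pass without NOS-null marrow replicates 1 and 3, Pdgfa without NOS-null marrow replicate 1 and Higd1b without NOS-null marrow replicate 4. Without both NOS-null marrow replicates 1 and 2 the HIF list was lower (adjusted p = 0.00409), and without WT marrow replicate 4 the endothelial list was higher (adjusted p = 0.0458).

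All 25 genes of the type I interferon list had a positive log2 change (median 0.65), and 8 rose while 17 did not pass. Mean deviations of this list were 0.68, 0.36, 0.09 and 0.38 in NOS-null marrow replicates 1 to 4 against −0.69 to −0.21 with WT marrow. Rsad2, the antiviral gene viperin, rose from 548 ± 102 to 1748 ± 312 (1.67, SE 0.16, adjusted p = 0.00199). Ifi44 rose from 57.6 ± 14.7 to 155 ± 18.5 (1.45, adjusted p = 0.00781), and the regulator genes Irf7 and Usp18 by 0.99 and 0.58 (adjusted p = 0.0219 and 0.016). Adjusted over the list alone 21 rose, and the list was higher than other genes (camera adjusted p = 2.18e-12, and adjusted p = 0.55 with an estimated correlation). Of 24 genes of the interferon gamma response and major histocompatibility complex (MHC) class I, all were positive (median 0.96) and 1 rose, the peptide transporter gene Tap2 (0.65, adjusted p = 0.0332). Adjusted over the list alone 20 rose (camera adjusted p = 2.37e-08, and adjusted p = 0.69 with an estimated correlation). The mean deviation of this interferon gamma list was 1.24 and 0.57 in NOS-null marrow replicates 1 and 2, 0.00 and −0.07 in replicates 3 and 4, and −0.48 to −0.41 with WT marrow. Without NOS-null marrow replicate 1 the median of the interferon gamma list was 0.52. Irf7 and Tap2 did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1 and 3, nor Irf7 without WT marrow replicate 4 and Tap2 without WT marrow replicate 2 (adjusted p up to 0.113). Usp18 did not pass without NOS-null marrow replicate 2 or WT marrow replicate 2 (highest adjusted p = 0.0566).

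Complement and acute phase genes were higher as a list of 17 (median 0.33, camera adjusted p = 0.0151, and adjusted p = 0.69 with an estimated correlation). The complement gene C4b rose from 905 ± 157 to 1726 ± 494 (0.90, adjusted p = 0.0305), 16 did not pass, and 5 rose and 1 fell adjusted over the list alone. The mean deviation of the complement list was 0.41 in NOS-null marrow replicate 2 and −0.08 to 0.07 in the other 3, against −0.35 in WT marrow replicate 4 and −0.07 to 0.02 in the other 3. Its median was 0.17 without NOS-null marrow replicate 2 and 0.50 without NOS-null marrow replicate 1. Genes of Toll-like receptor, NF-kB and inflammasome signalling were higher as a list of 24 (median 0.18, camera adjusted p = 0.0268, and adjusted p = 0.69 with an estimated correlation). Its riser was the inflammasome sensor gene Nlrp3 (26.4 ± 8.52 to 79.4 ± 38.7, 1.48, adjusted p = 0.0428), also the single riser adjusted over the list alone. The mean deviation of the Toll-like receptor list was 0.65 and 0.30 in NOS-null marrow replicates 1 and 2 and −0.19 and −0.06 in replicates 3 and 4, and its median was 0.11 without replicate 1 and 0.27 without replicate 2. The complement call was lost without WT marrow replicate 4 (adjusted p = 0.108). The Toll-like receptor call was lost without NOS-null marrow replicate 1 (0.148), without WT marrow replicate 4 (0.134) and without both NOS-null marrow replicates 1 and 2 (0.805). C4b and Nlrp3 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate, nor Nlrp3 without NOS-null marrow replicate 1 (adjusted p up to 0.123).

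Cytokine, chemokine, type 2 immunity, MHC class II and oxidative stress genes did not move as lists (camera adjusted p = 0.926, 0.204, 0.365, 0.143 and 0.106). None of 13 inflammatory cytokine genes passed, over all genes or adjusted over the list alone, with Il33 at 768 ± 447 against 1391 ± 127 (adjusted p = 0.115) and Il1b at 587 ± 335 against 259 ± 148 (adjusted p = 0.143). Of 26 chemokine genes 2 fell, over all genes and adjusted over the list alone. These were Cxcl12, which guides leukocytes and marrow cells (4584 ± 116 to 2408 ± 435, −0.95, SE 0.12, adjusted p = 0.00722), and Ccl21a (−0.55, adjusted p = 0.0457). Of 18 type 2 immunity genes, the mucus-associated gene Clca1 rose (1.62, adjusted p = 0.047) and Postn fell, with 2 rising and 3 falling adjusted over the list alone. The chemokine list was lower without NOS-null marrow replicate 2 (adjusted p = 0.0456), the MHC class II list higher without NOS-null marrow replicate 4 (0.0414) and the oxidative stress list higher without WT marrow replicate 1 (0.034). None of 10 MHC class II genes or 24 oxidative stress genes passed, with 6 rising and 2 falling and none, in turn, adjusted over the list alone. Ccl21a and Clca1 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate, nor Clca1 without NOS-null marrow replicate 1 (adjusted p up to 0.135).

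Marker genes of lymphocytes differed by lineage and by library. Of 10 NK and cytotoxic genes, 3 fell (median −1.002, camera adjusted p = 0.00439, and adjusted p = 0.69 with an estimated correlation), and 7 fell adjusted over the list alone. These were the receptor gene Klra8 (25.9 ± 7.92 to 3.30 ± 2.40, −2.73, SE 0.39, adjusted p = 0.00962), the granzyme gene Gzma (161 ± 21.4 to 68.0 ± 25.8, −1.29, adjusted p = 0.0191) and Klrb1c. Mean deviations of the NK list were −0.19, −0.23, −0.57 and −0.82 in NOS-null marrow replicates 1 to 4 against 0.25 to 0.80 with WT marrow. Klra8 and Klrb1c lie in the NK gene complex of chromosome 6. The mean log2 value of the 6 NK list members more than 10 Mb from Klra8 differed by −0.52, and the groups overlapped (exact permutation p = 0.0571). Klra8 belongs to a family of near-identical genes whose reads can be split in counting, so its value is uncertain. B cell genes were lower as a list of 15 (median −2.10, camera adjusted p = 2.39e-05, and adjusted p = 0.69 with an estimated correlation). There was no single B cell gene past the threshold, with 11 falling adjusted over the list alone. Their mean deviation was −2.65 and −1.21 in NOS-null marrow replicates 1 and 2, 0.14 and 0.19 in replicates 3 and 4, and 0.54 to 1.48 with WT marrow, and without NOS-null marrow replicate 1 the B cell median was −1.35. Cd79b, part of the B cell receptor, stood at 43.1, 89.5, 246 and 238 in NOS-null marrow replicates 1 to 4 against 457 ± 124. T cell genes were higher as a list of 20 (median 0.63, camera adjusted p = 0.000241, and adjusted p = 0.69 with an estimated correlation). No T cell gene passed over all genes or adjusted over the list alone. NOS-null marrow replicate 2 stood at a mean deviation of 1.33 against −0.06 to 0.09 in the other 3, and without it the T cell median was 0.29. Plasma cell genes did not move as a list of 7 (camera adjusted p = 0.665). Igj rose, while the secretory pathway genes Xbp1 (−0.37, adjusted p = 0.0423) and Txndc5 (−0.34, adjusted p = 0.0448) fell, over all genes and adjusted over the list alone. The plasma list's median (0.10) was positive while camera's direction was down. Gzma, Klrb1c, Igj, Xbp1 and Txndc5 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (adjusted p up to 0.137). Klrb1c, Igj and Xbp1 also did not pass without NOS-null marrow replicate 3, and Xbp1 and Txndc5 without NOS-null marrow replicate 1.

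Neutrophil genes were higher as a list of 14 (median 1.94, camera adjusted p = 1.88e-05, and adjusted p = 0.69 with an estimated correlation). No neutrophil gene passed over all genes, with 10 rising adjusted over the list alone. The mean deviation was 3.22 in NOS-null marrow replicate 1 and 0.76, −0.43 and 0.17 in replicates 2 to 4, against −1.48 to −0.38 with WT marrow. Without NOS-null marrow replicate 1 the neutrophil median was 1.29. The calprotectin gene S100a9 stood at 29866 scaled reads in NOS-null marrow replicate 1 and at 2961, 1490 and 1857 in replicates 2 to 4, against 788 ± 413. Monocyte genes were higher as a list of 20 (median 0.38, camera adjusted p = 0.0483, and adjusted p = 0.69 with an estimated correlation). No monocyte gene passed over all genes, with 1 rising and 1 falling adjusted over the list alone. The mean deviation was 0.75 in NOS-null marrow replicate 1 and −0.22 to 0.16 in replicates 2 to 4. The monocyte median was 0.22 without NOS-null marrow replicate 1 and 0.24 without WT marrow replicate 4. The monocyte call was lost without NOS-null marrow replicate 1 (adjusted p = 0.205), without WT marrow replicates 2 and 4 (0.0688 and 0.247) and without both NOS-null marrow replicates 1 and 2 (0.521). It was also lost with median-of-ratios size factors (adjusted p = 0.0507) and on FPKM (0.0514 and 0.0538 with added constants of 0.1 and 1). Platelet and megakaryocyte genes were lower as a list of 14 (median −0.51, camera adjusted p = 0.0103, and adjusted p = 0.69 with an estimated correlation). No platelet gene passed over all genes or adjusted over the list alone. The platelet call was lost without NOS-null marrow replicate 3 (adjusted p = 0.151). NOS-null marrow replicate 1 had a mean deviation of 0.79 against −1.19 to −0.37 in the other 3, and the platelet median was −0.88 without replicate 1 and −0.29 without replicate 3.

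Macrophage, dendritic cell and mast cell genes did not move as lists (camera adjusted p = 0.259 for alveolar macrophages, 0.12 for interstitial macrophages, 0.281 for dendritic cells and 0.842 for mast cells and basophils). Of 20 alveolar macrophage genes, the ribonuclease gene Ear2 rose (317 ± 55.9 to 600 ± 111, 0.92, adjusted p = 0.0186) and Siglec5 fell. In all, 5 rose and 2 fell adjusted over the list alone, and the list's median (0.23) and mean (−0.05) differed in sign. Of 15 interstitial macrophage genes, Lyve1 rose (0.65, adjusted p = 0.0415), with 1 rising and 2 falling adjusted over the list alone. Of 17 dendritic cell genes, Cd209a fell, with 1 rising and 2 falling adjusted over the list alone, and the list was lower without NOS-null marrow replicate 2 (adjusted p = 0.0167). None of 6 mast cell and basophil genes passed over all genes, and 1 fell adjusted over the list alone. With 4 tested genes the eosinophil list was too small for the list test. Siglec5 was its gene that fell, with 2 falling adjusted over the list alone. Ear2 and Lyve1 did not pass without NOS-null marrow replicate 2 or WT marrow replicates 2 and 3, nor Lyve1 without WT marrow replicates 1 and 4 (adjusted p up to 0.117).

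The erythroid list was higher than other genes (camera adjusted p = 5.76e-11, and adjusted p = 0.2 with an estimated correlation), with a higher mean deviation in each of the 4 NOS-null marrow libraries than in any with WT marrow. Of 19 genes tested, 12 rose, none fell and 7 did not pass, with a median log2 change of 1.07. Alas2, the first enzyme of haem synthesis in red cell precursors, rose from 2101 ± 183 to 5649.5 ± 979 (1.41, SE 0.12, adjusted p = 0.000975). The globin gene Hbb-b2 rose from 313 ± 47.4 to 778 ± 61.3 (1.32, adjusted p = 0.000975). Bpgm, the red cell bisphosphoglycerate mutase gene, rose from 832 ± 59.3 to 1551 ± 147 (0.89, adjusted p = 0.00205). These 3 genes passed in each of the 8 fits that left out 1 library, and Hbb-b2 is uncertain because globin genes are near-identical. In all, 15 rose and 1 fell adjusted over the list alone.

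Target genes of the p53 protein were higher as a list (camera adjusted p = 8.61e-08, and adjusted p = 0.2 with an estimated correlation). Of 15 p53 targets, 7 rose, none fell and 8 did not pass (median 0.63). Cdkn1a, the cell cycle inhibitor p21, rose from 1427 ± 180 to 4584 ± 1250 (1.65, SE 0.18, adjusted p = 0.00253), and Ccng1, cyclin G1, from 1252 ± 75.4 to 1937 ± 179 (0.63, adjusted p = 0.00781). Eda2r rose from 20.9 ± 4.17 to 118 ± 47.0 (adjusted p = 0.0092), and the stress-response gene Sesn2 from 55.0 ± 14.1 to 125 ± 10.4 (1.20, adjusted p = 0.0133). In the p53 list 12 rose and 1 fell adjusted over the list alone. All 24 proliferation genes had a negative log2 change (median −0.49), and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 9.89e-06, and adjusted p = 0.69 with an estimated correlation). Those with the smallest p were genes of the replicative helicase, Mcm2 (218 ± 39.3 to 111 ± 18.7, −0.97, adjusted p = 0.0182), Mcm6 (−0.58), Mcm3 (−0.60) and Mcm5 (−0.83). The mean deviation of the proliferation list was −0.83 in NOS-null marrow replicate 1, −0.11 to 0.06 in replicates 2 to 4, and −0.21 to 0.52 with WT marrow, and its median was −0.25 without replicate 1. The Mcm genes did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1, 2 and 3, nor Sesn2 without WT marrow replicate 1 (adjusted p up to 0.106).

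All 14 glucocorticoid targets were positive (median 0.82), with Cdkn1a, also a p53 target, the gene that rose. Adjusted over the list alone 9 rose (camera adjusted p = 9.89e-06, and adjusted p = 0.69 with an estimated correlation). Their mean deviation was 0.96 and 0.95 in NOS-null marrow replicates 1 and 2 and 0.00 and −0.11 in replicates 3 and 4, against −0.83 to 0.07 with WT marrow. Of 17 clock genes, the repressor gene Cry1 rose (156 ± 17.8 to 251 ± 43.2, 0.67, adjusted p = 0.0316), with 5 rising adjusted over the list alone (median 0.42, camera adjusted p = 0.00106, and adjusted p = 0.69 with an estimated correlation). Mean deviations of the clock list were 0.49, 0.23, 0.06 and 0.07 in NOS-null marrow replicates 1 to 4 against −0.38 to 0.01 with WT marrow. Per2 stood at 222 ± 34.96 against 118 ± 45.4 (adjusted p = 0.0526). Cry1 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (highest adjusted p = 0.106).

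Ciliated cell genes were higher as a list of 20 (median 0.22, camera adjusted p = 0.00934, and adjusted p = 0.69 with an estimated correlation), and this call was lost without WT marrow replicates 2 and 4 (adjusted p = 0.0518 and 0.0668). Mean deviations of the ciliated list were 0.02 to 0.18 with NOS-null marrow and −0.27 to 0.12 with WT marrow. The airway cadherin gene Cdhr3 rose (0.59, adjusted p = 0.045), with 4 rising adjusted over the list alone. Alveolar type 1, alveolar type 2 and club cell genes did not move as lists (camera adjusted p = 0.842, 0.0872 and 0.997). None of 14 type 1 genes passed over all genes or adjusted over the list alone, with the receptor gene Ager at 18444 ± 1040 against 17806 ± 626. Of 19 type 2 genes 1 fell, with 1 rising and 3 falling adjusted over the list alone. The type 2 list was lower without NOS-null marrow replicates 2 and 3 and WT marrow replicate 3 in turn (adjusted p = 0.0456, 0.0192 and 0.0444). The surfactant protein gene Sftpc stood at 82561 ± 12580 against 99604 ± 10400 (adjusted p = 0.274). Of 16 club cell genes, the cytochrome P450 genes Cyp4b1 (3556 ± 330 to 5557 ± 935, 0.63, adjusted p = 0.0296) and Cyp2a5 (73.8 ± 50.8 to 325 ± 169, 2.16, adjusted p = 0.0387) rose. In this list 2 rose and 1 fell adjusted over the list alone, and the list's median (−0.01) and mean (0.13) differed in sign. Cdhr3, Cyp4b1 and Cyp2a5 did not pass without NOS-null marrow replicate 2 or WT marrow replicates 1, 2 and 4 (adjusted p up to 0.137). Cdhr3 and Cyp2a5 also did not pass without NOS-null marrow replicate 1, and Cyp4b1 without WT marrow replicate 3.

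Lists for other tissue in the sample and for RNA handling were tested in the same way. Fibroblast, mesothelial, cardiac muscle, skeletal muscle, thymus, adipose and immediate early genes did not move as lists (camera adjusted p = 0.274, 0.12, 0.0738, 0.475, 0.208, 0.0557 and 0.538), but several of these passed when libraries were left out. Fibroblast genes were higher without NOS-null marrow replicate 1 (adjusted p = 0.00653), and mesothelial genes without NOS-null marrow replicate 1 or WT marrow replicate 1 (0.00562 and 0.00557). Cardiac genes were higher without NOS-null marrow replicates 2 and 4 and WT marrow replicate 3 in turn (adjusted p = 0.0456, 0.00116 and 0.000984), and adipose genes without NOS-null marrow replicate 4 or WT marrow replicate 3 (0.00641 and 0.000838). Without both NOS-null marrow replicates 1 and 2, fibroblast and mesothelial genes were higher (adjusted p = 0.000733 and 0.00442) and immediate early genes lower (0.0246). Of 16 fibroblast genes, Inmt, a methyltransferase gene, rose (6845 ± 842 to 9647 ± 953, 0.50, adjusted p = 0.0398) and was the riser adjusted over the list alone. It passed in 1 of the 8 fits that left out 1 library, that without NOS-null marrow replicate 4 (adjusted p up to 0.112 in the others). Of 7 mesothelial genes 1 rose and of 19 cardiac genes 1 fell, with 2 rising and 1 falling, in turn, adjusted over the list alone. None of 6 skeletal muscle, 6 thymus or 10 adipose genes passed over all genes, and 1 in each rose adjusted over the list alone. Of 17 immediate early genes 1 fell, also adjusted over the list alone. Of 3 tested airway cartilage and trachea genes, too few for the list test, 1 fell, and 2 fell adjusted over the list alone. Heat shock genes were lower as a list of 12 (median −0.37, camera adjusted p = 0.0264, and adjusted p = 0.69 with an estimated correlation). The chaperonin gene Hspe1 fell (−0.54, adjusted p = 0.0332), with 2 falling adjusted over the list alone. Mean deviations of the heat shock list were −0.59, −0.50, 0.14 and 0.36 in NOS-null marrow replicates 1 to 4 and −0.12, −0.13, 0.64 and 0.21 in WT marrow replicates 1 to 4, so the groups overlapped. The list's call was lost without NOS-null marrow replicates 1 and 2 in turn (adjusted p = 0.101 and 0.0901), without both (0.862) and without WT marrow replicates 3 and 4 in turn (0.181 and 0.0738). The heat shock median was −0.13 and −0.20 without NOS-null marrow replicates 1 and 2 in turn and −0.17 without WT marrow replicate 3. Hspe1 did not pass without NOS-null marrow replicate 2 or any 1 WT marrow replicate (highest adjusted p = 0.111).

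Ribosomal protein genes were lower as a list of 30 (median −0.09, camera adjusted p = 0.0154, and adjusted p = 0.72 with an estimated correlation). Mean deviations of the ribosomal list were 0.08, 0.01, −0.14 and −0.17 in NOS-null marrow replicates 1 to 4 against −0.04 to 0.25 with WT marrow. Rpl30 fell, over all genes and adjusted over the list alone, from 109 ± 19.7 to 54.1 ± 15.4 (−1.01, adjusted p = 0.0303). The list's call was lost without NOS-null marrow replicates 3 and 4 (adjusted p = 0.151 and 0.178), without WT marrow replicate 1 (0.365) and after a trend in GC content and length was removed (0.168), and its median was −0.05 without NOS-null marrow replicate 4 and −0.03 without WT marrow replicate 1. Rpl30 did not pass without any 1 WT marrow replicate (highest adjusted p = 0.106). No gene of the list of mitochondrially encoded genes was analysed here. As a sample check, the Y-linked gene Ddx3y stood at 1264 to 1700 scaled reads and the X-inactivation gene Xist at 14.8 to 102 in the 8 libraries. None of the 5 sex-linked genes passed, over all genes or adjusted over the list alone.

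**Figure D3:**
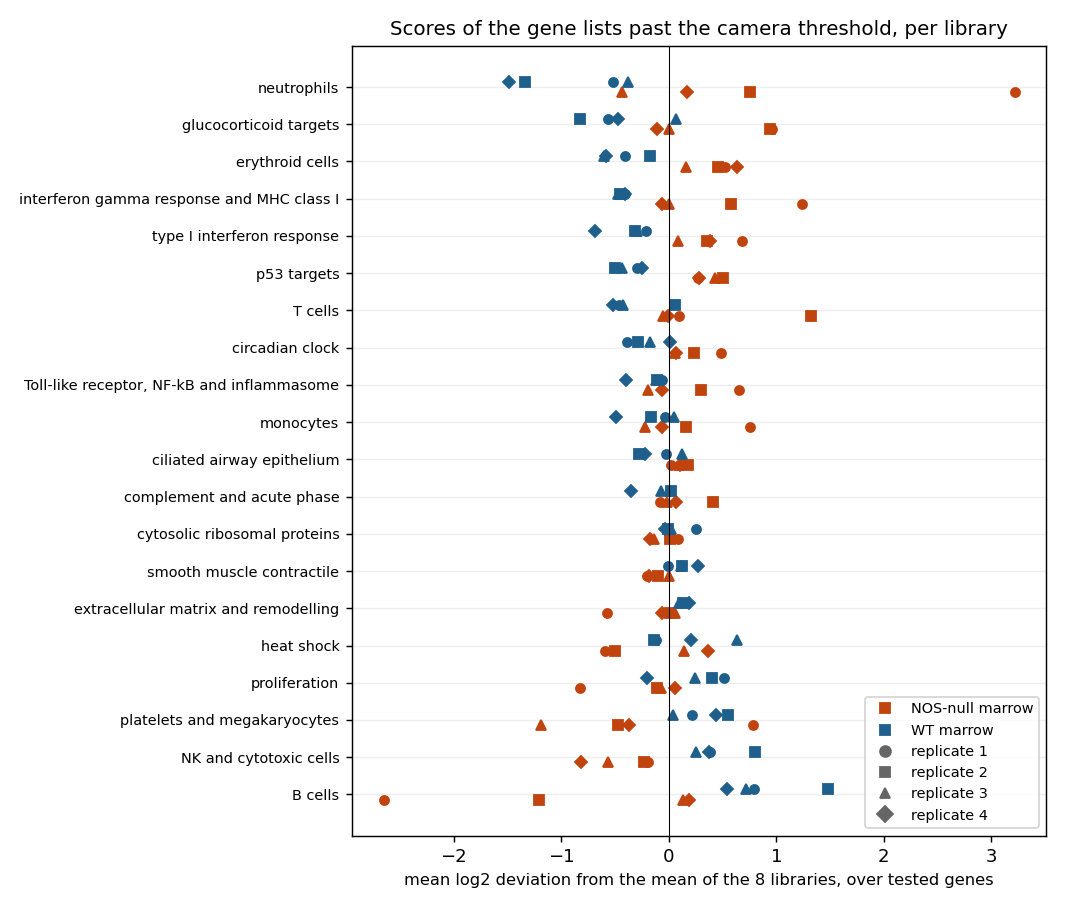
Mean log2 deviation of each tested gene from its mean over the 8 libraries, averaged within each of the 20 gene lists past the camera threshold (horizontal axis), with 1 point per library coloured by donor marrow and shaped by replicate. NOS-null marrow replicate 1 stands at 3.22 for neutrophils and −2.65 for B cells. The p53 target and erythroid lists separate all 4 libraries of each group. So do the type I interferon, interferon gamma, extracellular matrix, NK, B cell and clock lists.

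Of 45 lists tested, 12 were higher and 8 lower with camera at its preset correlation between genes, and none passed with a correlation estimated for each list (smallest adjusted p = 0.2; 3 at an unadjusted p under 0.05). Of the 20 lists, 13 passed in every fit that left out 1 library and 17 without both NOS-null marrow replicates 1 and 2. The rotation test fry, which asks whether the genes of a list move on balance in 1 direction, called 3 lists higher and 1 lower. Those higher were the type I interferon, p53 and erythroid lists, and the smooth muscle contractile list was lower. In 7 of the 35 splits of the libraries into 4 and 4, the real grouping among them, camera called as many lists or more. The highest other count was 23, so chance cannot be excluded for the number of lists.

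Called genes were not more frequent within 10 Mb of the deleted loci than elsewhere. Donor chromosomes can carry DNA there of the strain in which each gene was targeted. Within 10 Mb of Nos1, Nos2 or Nos3, 25 of 661 tested genes passed (3.78%), against 537 of 13257 elsewhere (4.05%), an odds ratio of 0.931 (95% interval 0.592 to 1.40, two-sided Fisher's exact p = 0.839). A difference within that interval was not detectable here. Nos2 itself is among the 25. At 5 Mb the share was 5.38% against 4.01% (odds ratio 1.36, 95% interval 0.777 to 2.24, two-sided Fisher's exact p = 0.244). At 20 Mb the odds ratio was 1.05, so its direction depended on the window. Donor DNA of another strain outside these windows was not covered.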

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

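The comparison of Klra8 and Klra18 with other NK genes, the Klra sums with genes left out and the erythroid against platelet comparison are tests chosen only after the result was seen. So are the fits without both NOS-null marrow replicates 1 and 2 and with a GC and length trend removed. The Klra, erythroid and smooth muscle patterns were picked from the results, and their other tests were set down before their own outcome was known. The groups, gene lists, main test and all other alternatives were fixed before the data were examined. Of 424 groups of 4 values checked with Dixon's test, 32 (7.55%) held a value standing apart from its group. For independent, normally distributed values chance gives about 1 in 20. Gene values were checked without log transformation and genes of a list vary together, so 7.55% is not shown to exceed chance. Of the 32, 12 lay in NOS-null marrow replicate 1 and 7 in replicate 2.

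In NOS-null marrow replicate 1 the values standing apart, with the range of the other 3 in brackets, were neutrophil or myeloid genes S100a9 29866 (1490 to 2961), Csf3r 2543 (354 to 669.5), Mmp9 2215 (212 to 377), Fpr2 1864 (290 to 445) and Pira1 1115 (99.4 to 128). The others in that library were the chemokine gene Ppbp 435 (85.8 to 144), Tap2 1086 (762 to 801), Per2 275 (203 to 207), Gata2 1372 (669 to 726), Klf4 2627 (1653 to 1727), Tnnt3 38.96 (28.3 to 29.2) and Eif2s3y 713 (557 to 564). In NOS-null marrow replicate 2 they were the T cell genes Cd6 210.3 (50.3 to 64.6), Cd28 152 (48.9 to 56.2), Cd5 163 (27.7 to 40.2) and Icos 204 (50.3 to 57.6), the T cell list at a mean deviation of 1.33 (−0.06 to 0.09), C3 8532 (4690 to 5317) and Hal 141 (40.2 to 56.2). In NOS-null marrow replicate 3 they were Klra8 6.90 (2.05 to 2.18) and Usp18 275 (299.9 to 302). In WT marrow replicate 2 they were Faim3 241 (130.1 to 146), Prf1 50.6 (28.8 to 31.2) and the T cell list at 0.058 (−0.52 to −0.43). In WT marrow replicate 3 they were Aplnr 1819 (282 to 355), Cdhr3 351 (244 to 249.6) and Tnnt3 80.8 (37.5 to 44.7). In WT marrow replicate 4 they were Irgm2 827 (617 to 645), Csf1r 642 (926 to 968), Ddx3y 1264 (1487 to 1518), the Toll-like receptor list at −0.40 (−0.12 to −0.07) and the pericyte list at 0.11 (−0.07 to −0.06).

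The fall of Klra8, with the related Klra18 at 0 in all NOS-null marrow libraries against a mean of 19.98 with WT marrow (at least 6.43-fold lower), could come from fewer NK cells, from reads moved to other Klra genes, or from donor DNA of another strain, since Klra genes are known to differ between inbred strains. Against the mean of the NK list members outside the gene complex, which itself differed by −0.52 (exact permutation p = 0.0571), the sum of Klra8 and Klra18 differed by a further −3.01 on the log2 scale (exact permutation p = 0.0286, the smallest possible with 4 against 4). Against Gzma it differed by −2.24 (exact permutation p = 0.0286, and −2.58 to −1.89 without 1 library). Klra8 and Klra18 were picked for their large fall, so these p-values give no independent support. Their values with NOS-null marrow were near the floor, and some NK list members are shared with T cells. The comparison therefore cannot decide whether fewer NK cells are the whole cause. The sum over 21 Klra genes differed by −0.34 (exact permutation p = 0.371; −0.63 without NOS-null marrow replicate 1 and −0.15 without replicate 3), by −1.71 without Klra2 and by −1.26 without Klra2, Klra8 and Klra18 (exact permutation p = 0.0286 for each). Klra2 made up 49.6% of that sum and stood at 239.9, 124, 63.1 and 80.5 in NOS-null marrow replicates 1 to 4 against 48.2 to 66.0 with WT marrow (limma adjusted p = 0.116). In replicate 3 Klra2 lay within the WT marrow range although Klra18 stood at 0, so no gain of Klra2 was seen in that library. Moved reads stay open for Klra2 in NOS-null marrow replicates 1, 2 and 4, while the other Klra genes together did not gain. Within 5 Mb of Klra8, Klr and Clec genes left out, called genes had an odds ratio of 2.35 (95% interval 0.729 to 5.88, two-sided Fisher's exact p = 0.0741; 5 of 56 against 554 of 13829), which neither excludes nor shows donor DNA of another strain, and an effect of the missing synthases stays open as untested.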

How the results depend on the processing

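Among those of the 567 called genes that an alternative tested, none had the opposite sign; for results that did not keep, the cause was not tested. Called genes numbered 424 to 835 under other scalings, filters, limma options and FPKM (402 higher with array weights), 1826 at adjusted p under 0.1 (881 higher, 945 lower), and 304 at 1.5-fold or more (170 and 134). Without 1 library they numbered 71 to 798 (44 higher and 27 lower without WT marrow replicate 1, 411 higher without NOS-null marrow replicate 4, 389 lower without NOS-null marrow replicate 3), and Nos2 changed by −2.08 to −1.53. Without both NOS-null marrow replicates 1 and 2, a choice made after the result was seen, 181 genes were called (97 and 84). With the replicate number as a replicate block they numbered 135 (81 higher and 54 lower, 128 shared with the 567). Deviations from the group mean correlated at 0.0428, 0.169, −0.00266 and 0.151 for pairs of equal number. For the other pairs across groups they correlated at −0.18 to 0.112. Not every library correlated best with its own number, but this does not exclude pairing. The groups were not taken as paired because the labels do not say that equal numbers mark pairs. In the 35 splits of the libraries into 4 and 4, 1 split, the real grouping, had any called gene (567, highest other 0; at unadjusted p under 0.05 3723, highest other 1550), which is not likely by chance. For lists 7 of the 35 splits called as many or more (real 20, highest other 23), so chance cannot be excluded for the number of lists. Camera with estimated correlation called 0 higher and 0 lower, and fry 3 and 1. The odds ratio near the Nos genes was 1.36 at 5 Mb (two-sided Fisher's exact p = 0.244), 1.05 at 20 Mb, 1.11 with quantile normalization, 1.06 with library totals, 1.04 with robust limma and 1.04 with both FPKM forms, and 0.217 to 1.23 without 1 library. Reversed list medians were alveolar type 1 −0.0155 (quantile) and −0.0056 (GC and length trend), fibroblasts −0.0079 (quantile), −0.0212 (library totals) and −0.0338 (GC), plasma cells −0.0067 (no filter) and −0.2086 (mean of at least 50), mast cells 0.2431 (no filter) and 0.0342 (FPKM), alveolar type 2 0.0082 (array weights) and 0.0116 (without both), pericytes 0.0553 (array weights) and 0.0619 (without both), heat shock 0.1605 (without both), and club cells 0.0125 (without both) and 0.009 (GC). Without 1 library the medians ran, for dendritic cells, from −0.3591 to 0.0618, plasma cells −0.1655 to 0.386, mast cells −0.2075 to 0.012, fibroblasts −0.0601 to 0.165, pericytes −0.0607 to 0.0621, club cells −0.0446 to 0.0333, immediate early genes −0.1383 to 0.0673 and vasoactive genes −0.0215 to 0.1335. Reversed genes with array weights were Sod3 0.0997, Alox15 0.069, Sftpb 0.0082, Mfap4 0.0047 and Eif2s3y −0.0237. Without both replicates they were Gpx3 −0.1248, Sod3 0.0829, Alox15 0.6323, Sftpb 0.0116, Mfap4 0.1189, Ddx3y −0.0432 and Eif2s3y −0.0262, and with the GC and length trend removed Nos3 −0.005. Without 1 library the ranges were Sod3 −0.2358 to 0.0435, Alox15 −0.7593 to 0.2627, Mfap4 −0.2546 to 0.0814, Actc1 −0.087 to 0.2411, Ier3 −0.3951 to 0.1948, Klf4 −0.2521 to 0.0375 and Eif2s3y −0.0255 to 0.1012. The alternatives planned for unscaled read counts were not run, because the values were already scaled.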

Other observations

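The tubulin, endoplasmic reticulum and Gimap groups, the genes named beside them, the tests of these groups and the erythroid against platelet test were chosen only after the result was seen. The camera p-values of these groups are unadjusted. They come from the same values that led to the choice of the groups, so they give no independent support. Tubulin genes, which build the cytoskeleton and the spindle, were lower: of 14 tested, 7 fell and none rose, among them Tubb5 (−0.65), Tubb6 (−1.27) and Tuba1a (−0.77). Camera gave an unadjusted p = 6.52e-08, and an unadjusted p = 0.0438 with an estimated correlation. Genes of protein folding and export in the endoplasmic reticulum were lower as well, with 14 of 45 falling and 42 negative, among them Pdia6 (−0.69), Kdelr3 (−1.15), Hspa5 (−0.57) and Calr (−0.40), and camera p = 1.33e-14 (p = 0.026 with an estimated correlation). Of 8 Gimap genes, lymphocyte GTPases that lie side by side, Gimap4 (−0.59), Gimap8 (−0.52) and Gimap6 (−0.32) fell, with camera p = 0.000805 (p = 0.0934 with an estimated correlation). NOS-null marrow replicates 1 to 4 stood at 257, 319, 505 and 536 for Tubb6 (840.4 to 1027 with WT marrow), at 122, 129, 239 and 241 for Kdelr3 (363 to 414) and at 4617, 4928, 5938 and 6327 for Hspa5 (7368 to 8647). The tubulins falling numbered 3 without NOS-null marrow replicate 2, 2 without WT marrow replicate 3, and 0 without WT marrow replicate 1 or 2 (8 of 14 in limma at an unadjusted p under 0.05 in each). The folding and export genes falling numbered 1 without NOS-null marrow replicate 2 or WT marrow replicates 1, 2 and 3, 5 without WT marrow replicate 4 and 4 without both NOS-null marrow replicates 1 and 2. The Gimap genes falling numbered 1 without NOS-null marrow replicate 2 or any 1 WT marrow replicate and without both NOS-null marrow replicates 1 and 2.

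BC018473, a non-coding RNA gene, stood at 166 with NOS-null marrow and 0.234 with WT marrow (limma adjusted p = 3.11e-05). The WT marrow value of BC018473 rests on 1 read, so the ratio of the pooled reads, 688, has an exact 95% counting interval of 123 to 27200. This interval covers counting error only and leaves out the spread between mice. Other large changes were Gm5506 (3.74), 9930013L23Rik (−3.64), Chodl (−3.48) and Klra7 (−2.18). Fmo2 (1.37), Hpgd (1.11), Ucp2 (1.19) and Ephx1 (0.80), genes of oxidation, prostaglandin breakdown, mitochondria and epoxide breakdown, rose. Serpinh1, a collagen chaperone gene (−1.08), Lgals1 (−0.96), Ankrd1 (−0.93) and the sodium channel gene Scn7a (−0.90) fell. Amd1 was listed at 1.48 and 1.47 in NOS-null marrow replicates 3 and 4 and at 1243 to 2489 elsewhere, beside its near-identical copy Amd2 at 1003 to 4593, so its value is uncertain.

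The rise of erythroid genes may come from more blood left in the lung, from a larger number of young red cells in blood, or from red cell formation in the lung. More blood would raise platelet genes too, yet the erythroid list rose by 0.889 on the log2 scale (exact permutation p = 0.0286) and the platelet list stood at −0.621 (exact permutation p = 0.2; −0.986 without NOS-null marrow replicate 1 and −0.329 without replicate 3). Their difference was 1.51 (exact permutation p = 0.0286, the smallest possible, and 1.31 to 1.85 without 1 library). Both list results were known when this comparison was chosen, so its p-value gives no independent support. The comparison also needs the 2 marrow types to make equal numbers of platelets, which was not measured. Platelet scores of NOS-null marrow replicates 2 to 4 (5.61, 4.89 and 5.71) lay below every WT marrow library (6.12 to 6.63). It therefore cannot decide whether more blood was left in the lung. In NOS-null marrow replicate 1 both scores, 9.33 for erythroid and 6.87 for platelet genes, lay above those of every WT marrow library (at most 8.64 and 6.63), so more blood in that library stays open as well. The explanations of more young red cells in blood and of red cell formation in the lung were not separated by any test, and blood counts were not analysed here.

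The fall of contractile genes could come from a lower share of smooth muscle in the sampled lung, from lower contractile gene activity within these cells, or from fewer newly muscular small vessels. With a lower share alone the list members would fall alike, yet 6 members had a 95% interval wholly above the list median of −0.41 and 2, Acta2 and Tagln, wholly below it. Those above were Myh11 (−0.17), Mylk (−0.07), Synpo2 (0.28), Lmod1 (0.35), Notch3 (0.44) and Myocd (0.62). This argues against a lower share alone, although some members are also made by other cells. Acta2 and Tagln may report activated fibroblasts and new vessel muscle as well, which whole-lung RNA cannot tell apart.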
